A study of Mus musculus with 24 samples.

How the data were processed

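The series measured mouse splenic B cells with RNA-seq and with several assays of transcription and chromatin. RNA-seq libraries of 3 WT and 3 Spt5-depleted cultures were analysed here, and the 18 samples of the other assays were not analysed here. Groups were taken from the sample labels. The labels call the cells mature in one field and immature in another, so maturity is left open.

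Per the labels' protocols, total RNA was extracted with Trizol and libraries were made from poly(A) RNA with a Lexogen SENSE mRNA-seq kit. Per the submitters' processing notes, cutadapt 1.10, Bowtie2 2.1.0, TopHat, featureCounts 1.5.0-p1, DESeq2 1.10.1 and the mouse build mm9 were used; the role of each tool, the annotation, the strand setting and the handling of reads that map to several places are not given in the sources used here. The deposited table gives whole read counts per gene for each library, without normalisation by the authors. It also holds the authors' log2 fold change and the authors' adjusted p-value for each gene, which were used only where the authors' deposited table is named. The table has 14106 genes, and each has at least 10 counts over the 6 libraries, so genes below that are not in it. Gene names were taken from the table with their suffixes removed. A suffix that may mark overlap with another gene is on 2005 names, and overlapping genes, paralogs and immunoglobulin genes can share reads in ways the counting does not resolve. Gene positions are not given, because the annotation at hand is of another build.

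Counts were analysed in R 4.3.3 with edgeR 4.0.16, limma 3.58.1 and DESeq2 1.42.0. Genes with low counts were removed with edgeR's filterByExpr, which left 12024 genes. Libraries were scaled by TMM, which assumes that most genes do not change; without spike-in RNA a change in total mRNA per cell would not be seen. The scaling factors were 0.949, 0.943 and 0.947 for WT and 1.035, 1.057 and 1.078 for Spt5-depleted libraries. Groups were compared with edgeR's quasi-likelihood F test with robust estimation, two-sided, and p-values were adjusted by the Benjamini-Hochberg method over all tested genes with a threshold of 0.05. Levels are given as TMM-normalised CPM with the SD over libraries, and standard errors of log2 fold changes were computed from the F statistic. The biological coefficient of variation was 0.098.

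Before the data were examined, 31 gene lists, the test, its alternatives and the rule for naming genes were fixed. Lists with at least 5 tested members were tested with limma's camera on voom values with a preset inter-gene correlation of 0.01, adjusted over 27 lists, and again with an estimated correlation and with fry, which asks whether a list's genes move on balance one way and compares them with no other genes. Named genes are Supt5; the 10 largest rises and the 10 largest falls among genes that passed, had a mean of at least 5 CPM and had no overlap between groups; up to 2 risen and 2 fallen members of each tested list with the smallest p; and Myc, Prdm1, Irf4, Bach2, Pax5, Xbp1, Ighm, Trp53 and Cdkn1a whatever they showed. Some genes that this rule names are not reported here. Alternatives were DESeq2's size factors, library totals alone, upper-quartile factors, no filter, a mean of at least 5 CPM, DESeq2's Wald test, limma-voom, the replicate number as a block, a 2-fold minimum, an adjusted p under 0.01, and leaving out each library. A planned test of fold change against gene length was not run, because lengths for the authors' build were not at hand.

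Replicates were checked before they were averaged: each pair within a group differed by more than sampling noise, with chi-square per degree of freedom between 6.46 and 33.2. The tests were tried on 1 simulated data set for this comparison with 200 changed genes among 11908 tested. There, 4.17% of genes changed 1.2-fold, 60.0% of those changed 1.5-fold, 91.8% of those changed 2-fold and 98.0% of those changed 4-fold were recovered, and 8.90% of all calls were false, against a nominal 5%. With 1 simulated data set and few changed genes, that share is a single draw and not an estimate of the error rate. Far fewer genes changed there than were called in the data, which makes the adjusted threshold stricter. The recovered shares therefore do not carry over to the real comparison. A list raised by 1 on the log2 scale was recovered by camera, and 0 of 25 lists without its genes were called. Each gene was drawn independently there, so this does not show how often camera calls lists whose genes vary together.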

Results

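The data were read counts per gene from poly(A) RNA of mouse splenic B lymphocytes, activated in culture with interleukin 4 and lipopolysaccharide. The cells were activated for 28 h and then kept with 2 µM 4-hydroxytamoxifen for another 32 h, which makes 60 h of activation in all. In 3 libraries the cells carried a floxed and a null allele of the gene for Spt5 together with a tamoxifen-activated Cre recombinase, and they are called Spt5-depleted here. In the 3 control libraries, called WT, the cells carried the recombinase alone and received the same drug. Spt5 is a subunit of DSIF, a factor that binds RNA polymerase II during pausing and elongation. The comparison asks how the mRNA of activated B cells differs after the gene for Spt5 has been targeted. Spt5 protein is not measured by these counts. WT cells lacked the null allele, so its effects cannot be told apart from those of the induced deletion. The WT libraries held 25036970, 23340978 and 25649611 counts. The Spt5-depleted libraries held 17306549, 20216180 and 21441575, so each depleted library was shallower than each WT library. The labels do not say whether the libraries of a group came from separate animals, so p-values measure only the spread between these libraries, which may be technical.

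Supt5, the targeted gene, had 3796, 3512 and 4666 counts in the WT libraries and 189, 196 and 314 counts in the Spt5-depleted libraries. Its mean was 170.5 ± 18.7 CPM (normalised read count; SD, n = 3) in WT and 11.1 ± 2.25 (SD, n = 3) in depleted cells, a 15.3-fold lower level (log2 fold change -3.94 ± 0.14 SE, edgeR adjusted p = 1.23e-10). Supt4a, which encodes the partner of Spt5 in DSIF, rose from 110 ± 12.3 to 296 ± 18.5 CPM (SD, n = 3 each; log2 fold change 1.43 ± 0.10 SE, adjusted p = 1.70e-08). Of 12024 genes tested, 3822 were higher and 3685 lower in Spt5-depleted cells at an adjusted p under 0.05. At least 2-fold changes were found for 1187 of the higher and 917 of the lower genes. The values of the 3 depleted libraries lay wholly above or below those of the 3 WT libraries for 8119 tested genes, 67.5% of them, where chance gives 10%. Scaled by library totals alone, which moves the median log2 fold change of all genes from 0.005 to 0.164, 4961 genes were higher and 2694 lower. The share of calls that were higher was then 64.8%, against 50.9% in the fit reported here. TMM assumes that most genes do not change, and 62.4% of tested genes were called. The near-even 50.9% therefore depends on the scaling and does not show that rises and falls were balanced.

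The X-linked RNA Xist and the Y-linked genes divided the libraries exactly as the genotype did. Xist, the RNA that coats the inactive X chromosome, had 625, 914 and 468 CPM in the WT libraries and 1.00, 1.31 and 1.73 CPM in the Spt5-depleted libraries. Among genes with a mean of at least 5 CPM and no overlap between the groups, the 4 largest rises were those of the Y-linked genes Ddx3y, Eif2s3y, Uty and Kdm5d. Summed over the 3 libraries of a group, Ddx3y had 1 count in WT and 2569 in depleted cells, Eif2s3y 3 and 3040, Uty 1 and 1111, and Kdm5d 2 and 1888. The X-linked gene Mid1 fell from 46.3 ± 13.4 to 2.52 ± 0.20 CPM (SD, n = 3 each; adjusted p = 5.94e-08). Its log2 fold change was -4.19. The X-linked genes Kdm5c, Ddx3x, Eif2s3x and Kdm6a, which the naming rule does not include, fell less (-1.12, -0.96, -0.86 and -0.63). Why Mid1 fell further was not tested. Every difference between the groups described here is therefore also a difference between libraries with Xist RNA and libraries with Y-linked mRNA, and the labels do not give the sex of the mice.

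Under the same minimum of 5 CPM and without overlap, the next largest rise was that of Hist2h2be, a histone H2B gene, at 4.18 ± 0.32 CPM in WT and 103 ± 4.37 CPM in depleted cells (SD, n = 3 each; log2 fold change 4.62 ± 0.11 SE, adjusted p = 7.17e-13). Libraries were made from poly(A) RNA, so Hist2h2be transcripts without a poly(A) tail may be missed. Slc18a1, a vesicular monoamine transporter, Lrrc51, 0610009L18Rik, D130020L05Rik and Pmel, a melanosome protein, completed the 10 largest rises, with log2 fold changes of 4.06, 3.93, 3.68, 3.63 and 3.53. The largest fall under that rule after Xist was that of Trib3, a pseudokinase induced by amino acid shortage, which went from 23.4 ± 4.05 to 1.04 ± 0.09 CPM (SD, n = 3 each; log2 fold change -4.49 ± 0.18 SE, adjusted p = 1.23e-10). Slc16a3, a lactate exporter, had a log2 fold change of -4.11, Asns, the asparagine synthetase, -3.57, and Gpt2, a mitochondrial alanine aminotransferase, -3.50. Slc6a9, a glycine transporter, stood at -3.38, Ighg1, the immunoglobulin gamma 1 constant region, at -3.36 (adjusted p = 1.53e-12), and Aldh1l2, a mitochondrial folate enzyme, at -3.21. The rows for Xist, D130020L05Rik, Pmel and Slc6a9 carry a suffix on their names that may mark overlap with another gene, so reads of a neighbour are not excluded there. Among genes named below, the rows for Tpi1, Bach2, Atf5, Tk1, Foxm1, Gbp2 and Lck carry the same suffix.

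**Figure D1:**
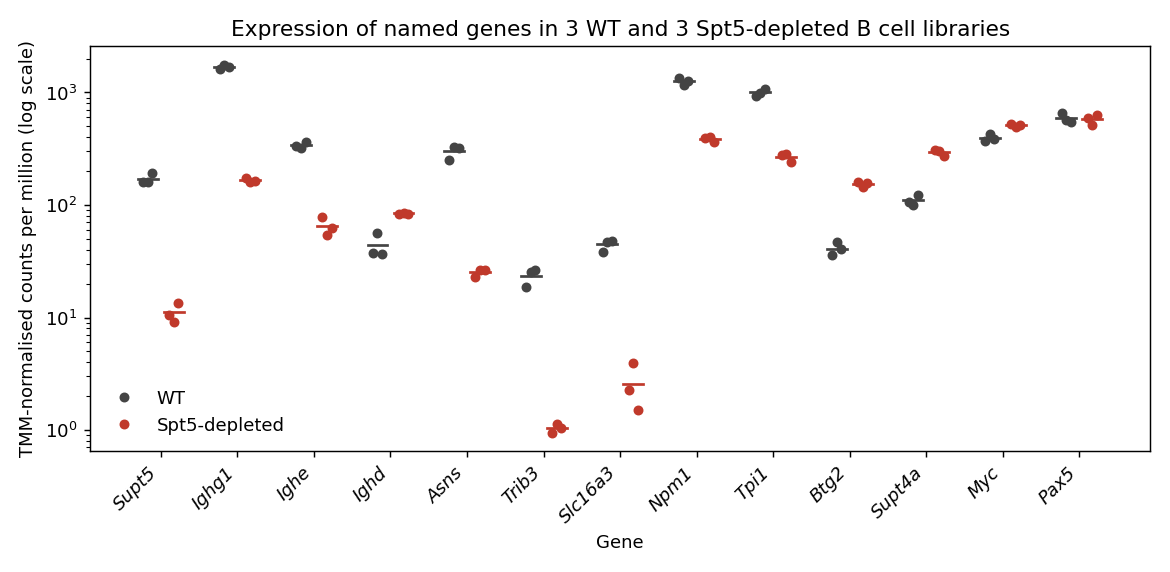
TMM-normalised CPM on a log axis for named genes, with a point for each library (WT in grey, Spt5-depleted in red, n = 3 each) and a bar at each group mean. Supt5, Ighg1 and Asns lie lower in all 3 depleted libraries than in any WT library, Btg2, Supt4a and Ighd lie higher, and the Pax5 values of the 2 groups overlap.

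Genes are grouped in what follows by lists fixed before the data were examined. Abundant genes tended to be lower whatever their list. Without the filter on low counts, the 578 genes above 300 CPM had a median log2 fold change of -0.26, with 298 lower and 114 higher. The 1808 genes from 100 to 300 CPM had a median of -0.07. Camera did not match lists to genes of like abundance, so small falls of lists of abundant genes are not shown to exceed this trend. Counts of members that rose or fell were the same when adjusted over the list alone, except where a second pair of numbers is given.

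Constant region genes of the immunoglobulin heavy chain differed between the groups. Ighg1 fell from 1690 ± 67.8 to 165 ± 7.45 CPM and Ighe, the epsilon constant region, from 340 ± 19.3 to 64.7 ± 12.0 CPM (SD, n = 3 each; adjusted p = 1.92e-09), while Ighd rose from 43.7 ± 11.1 to 84.0 ± 1.43 CPM (adjusted p = 0.000117). Ighg2b and Ighg3, chosen after their values were seen, had log2 fold changes of -1.54 and -1.04 (adjusted p = 0.00107 and 0.000222). Of 10 tested immunoglobulin constant regions 8 fell, 1 rose and 1 did not pass (median log2 fold change -0.93, limma camera adjusted p = 0.00335). Its camera test had an adjusted p = 0.52 with an estimated correlation. Ighm fell from 27830 ± 10260 to 15120 ± 1235 CPM (SD, n = 3 each; log2 fold change -0.88 ± 0.24 SE, adjusted p = 0.0117), a call lost without Spt5-depleted replicate 1 (log2 fold change -0.88, adjusted p = 0.0653). These counts do not separate the transcripts of switched loci from sterile germline transcripts of the same constant regions. In the list of class switching and DNA break factors 20 of 32 tested genes fell and 6 rose, with 21 and 6 adjusted over the list alone (camera adjusted p = 0.00335). The same test gave this list an adjusted p = 0.41 with an estimated correlation. Nbn, of the complex that binds DNA breaks, fell from 63.3 ± 6.04 to 18.8 ± 0.41 CPM, and Xrcc5, the Ku80 subunit, rose from 42.3 ± 1.28 to 72.3 ± 3.36 CPM (SD, n = 3 each; adjusted p = 3.02e-09 and 2.37e-06).

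The B cell identity list went both ways, with 7 of 32 tested genes higher and 15 lower (median log2 fold change -0.13, camera adjusted p = 0.0832), and was called lower without WT replicate 3 or Spt5-depleted replicate 1 (adjusted p = 0.0462 and 0.0381). With library totals alone 12 were higher and 13 lower, and the median was 0.03. Cd22, an inhibitory receptor, and Irf8 fell (log2 fold changes -1.48 and -1.52), and Spib and Cr2, the complement receptor, rose (1.15 and 1.05). Pax5, the B lineage regulator, stood at 591 ± 57.7 and 584 ± 60.5 CPM (SD, n = 3 each; adjusted p = 0.891), and Bach2, which restrains plasma cell differentiation, fell from 98.3 ± 11.1 to 39.6 ± 2.36 CPM (adjusted p = 5.15e-08). The plasma cell list was lower, with 11 of 20 genes down and 2 up (median -0.54, camera adjusted p = 0.00789). That list's camera test had an adjusted p = 0.65 with an estimated correlation. Its members Irf4 and Sdc1 rose (log2 fold changes 0.37 and 0.65), Xbp1 and Creld2, which act in the secretory pathway, fell (-0.70 and -1.25), and Prdm1 had 78.5 ± 16.3 and 81.0 ± 8.73 CPM (SD, n = 3 each; adjusted p = 0.774). Of 17 tested genes of the interleukin 4 response 8 fell and 6 rose (camera adjusted p = 0.344), with Il4ra, the receptor chain, at -2.16 and Socs2 at -1.98 against Id2 at 2.22 and Socs1 at 1.24. Of 16 MHC class II presentation genes 6 fell, among them H2-Ab1 (-0.80) and H2-Eb1 (-0.78), and 2 rose, Ctss (0.62) and Ifi30 (0.54) (camera adjusted p = 0.385). With library totals alone the medians of the interleukin 4 and MHC class II lists turned from -0.02 to 0.14 and from -0.05 to 0.10, with 6 higher and 7 lower genes in the first and 5 and 6 in the second.

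The integrated stress response list, genes induced by ATF4 when amino acids are short, was lower. Of its 30 tested genes 26 fell and 1, Atf5, rose (median log2 fold change -1.29, camera adjusted p = 3.75e-10). Its test gave an adjusted p = 0.41 with an estimated correlation. Asns fell from 300.3 ± 42.6 to 25.2 ± 2.08 CPM (SD, n = 3 each; adjusted p = 1.55e-11). The glycolysis list had 15 of 18 genes lower and 0 higher (median -1.34, camera adjusted p = 8.89e-09). For this list camera gave an adjusted p = 0.41 with an estimated correlation. Tpi1, triose phosphate isomerase, went from 1001 ± 74.7 to 267 ± 21.5 CPM and Pfkl, a phosphofructokinase, from 72.4 ± 4.68 to 19.5 ± 1.47 CPM (SD, n = 3 each; adjusted p = 9.40e-10 and 1.22e-09).

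Of 38 tested genes of the list of MYC targets and ribosome biogenesis 33 fell (median log2 fold change -0.74, camera adjusted p = 8.94e-10). The test of this list gave an adjusted p = 0.52 with an estimated correlation. Npm1, nucleophosmin, fell from 1258 ± 87.9 to 385 ± 22.7 CPM and Srm, spermidine synthase, from 616 ± 82.0 to 205 ± 7.49 CPM (SD, n = 3 each; adjusted p = 1.66e-09 and 8.07e-09). Myc itself was the 1 member that rose, from 395 ± 28.1 to 513 ± 16.8 CPM (SD, n = 3 each; log2 fold change 0.38 ± 0.09 SE, adjusted p = 0.0014). Of 77 cytosolic ribosomal protein genes 46 fell and 0 rose, with Rpsa at -0.98 and Rps7 at -1.54 (median -0.35, camera adjusted p = 7.24e-07). Here camera gave an adjusted p = 0.63 with an estimated correlation. Genes of this family share reads with processed pseudogenes, so single members are uncertain. The endoplasmic reticulum stress list had 18 of 24 genes lower and 2 higher (median -0.59, camera adjusted p = 1.14e-05; adjusted p = 0.52 with an estimated correlation), with Hyou1 and Sdf2l1, chaperone system genes, at -1.21 and -1.19 and Dnajb9 at 0.62. Of 22 heat shock and chaperone genes 16 fell and 2 rose (median -0.52, camera adjusted p = 0.000738). For these genes camera gave an adjusted p = 0.52 with an estimated correlation. Hspa8 and Hsp90ab1, which are expressed without stress, fell (-1.53 and -1.05), and the near-identical inducible genes Hspa1a and Hspa1b rose from 0.37 and 0.48 CPM to 1.65 and 1.74 CPM. The oxidative phosphorylation list was not called, with 11 of 34 genes higher and 6 lower (median 0.11, camera adjusted p = 0.421), among them Uqcrfs1 (0.61) and Atp5b (-0.64). With library totals alone 19 were higher and 1 lower (median 0.26).

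Genes of the cell cycle were also lower as groups, and whether they fell beyond other genes of like abundance was not tested. Of 35 DNA replication genes 26 fell and 2 rose (median log2 fold change -0.41, camera adjusted p = 1.14e-05; adjusted p = 0.41 with an estimated correlation), with Rrm2, a ribonucleotide reductase subunit, at -1.24, Gins1 at -1.10 and Tk1 at 0.44. Of 30 mitosis genes 18 fell and 2 rose, with 19 and 2 adjusted over the list alone (median -0.31). Camera gave the mitosis list an adjusted p = 0.00129, and an adjusted p = 0.41 with an estimated correlation. Top2a stood at -1.15, Cenpa at -0.92 and Foxm1 at 0.59. Scaled by library totals alone, 11 mitosis genes were lower and 3 higher (median -0.15). Of 39 replication-dependent histone genes 17 fell, including Hist1h1b (-1.95), and 9 rose (median -0.38, camera adjusted p = 0.402). The counts come from poly(A) RNA, so histone transcripts without a poly(A) tail may be missed. The median and mean of the histone list were negative and fry gave the direction up (adjusted p = 0.649). Of 27 p53 target genes 9 rose and 4 fell (median 0.14, camera adjusted p = 0.268), with Tnfrsf10b at 1.22 and Sesn2, also an ATF4 target, at -1.04. Library totals alone gave 15 higher and 4 lower p53 target genes (median 0.3). Cdkn1a rose from 69.2 ± 5.03 to 96.6 ± 3.10 CPM and Trp53 had 362 ± 21.2 and 405 ± 22.5 CPM (SD, n = 3 each; adjusted p = 0.000221 and 0.117), the latter passing with library totals alone (adjusted p = 0.00393). Of 16 BCL2 family genes 5 rose and 3 fell, with 8 and 4 adjusted over the list alone (camera adjusted p = 0.435), led by Bmf (1.65) and Pmaip1 (0.74). Under library totals alone 8 BCL2 family genes were higher and 1 lower (median 0.34, against 0.18).

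The immediate early genes were the 1 list called higher, with 20 of 32 genes up and 6 down (median log2 fold change 0.61, camera adjusted p = 0.0017). The list's camera test had an adjusted p = 0.52 with an estimated correlation. Btg2, an antiproliferative gene, rose from 41.0 ± 5.64 to 153 ± 7.93 CPM and Dusp6, a phosphatase of the ERK pathway, from 9.46 ± 1.37 to 37.3 ± 3.55 CPM (SD, n = 3 each; adjusted p = 1.97e-09 and 7.16e-09), while Klf2 (-0.78) and Jund (-0.52) fell. Lists of other signalling and transcription genes went both ways and were not called. Of 36 NF-kB response genes 16 fell, including Nfkb1 (-1.64) and Birc3 (-1.09), and 10 rose, including Ccr7 (1.79) and Tnf (1.51) (camera adjusted p = 0.506). Of 40 interferon response genes 13 rose and 12 fell, with 14 and 12 adjusted over the list alone (median -0.03, mean 0.07, camera direction up, adjusted p = 0.764), and Ifit1 (1.65) and Ifit2 (1.95) moved against Gbp2 (-1.93) and Gbp3 (-0.80). Of 33 elongation factor genes 7 rose, including Aff1 (1.18), a scaffold of the super elongation complex, and 12 fell, including Larp7 (-0.83) and Ssrp1 (-0.67) (camera adjusted p = 0.657). Of 34 genes for RNA polymerase II subunits and initiation factors 9 rose, with Gtf2a1 at 1.29 and Polr2g at 0.98, and 10 fell, with Gtf2h4 at -0.66 and Mnat1 at -0.54 (median -0.01, mean 0.07, camera direction up, adjusted p = 0.853). The balance of these 4 lists depended on the scaling. With library totals alone 13 NF-kB response genes were higher and 11 lower, 17 and 7 interferon response genes (median 0.14), 14 and 8 elongation factor genes (median 0.15, against -0.01), and 12 and 5 genes for polymerase subunits and initiation factors (median 0.15).

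**Figure D2:**
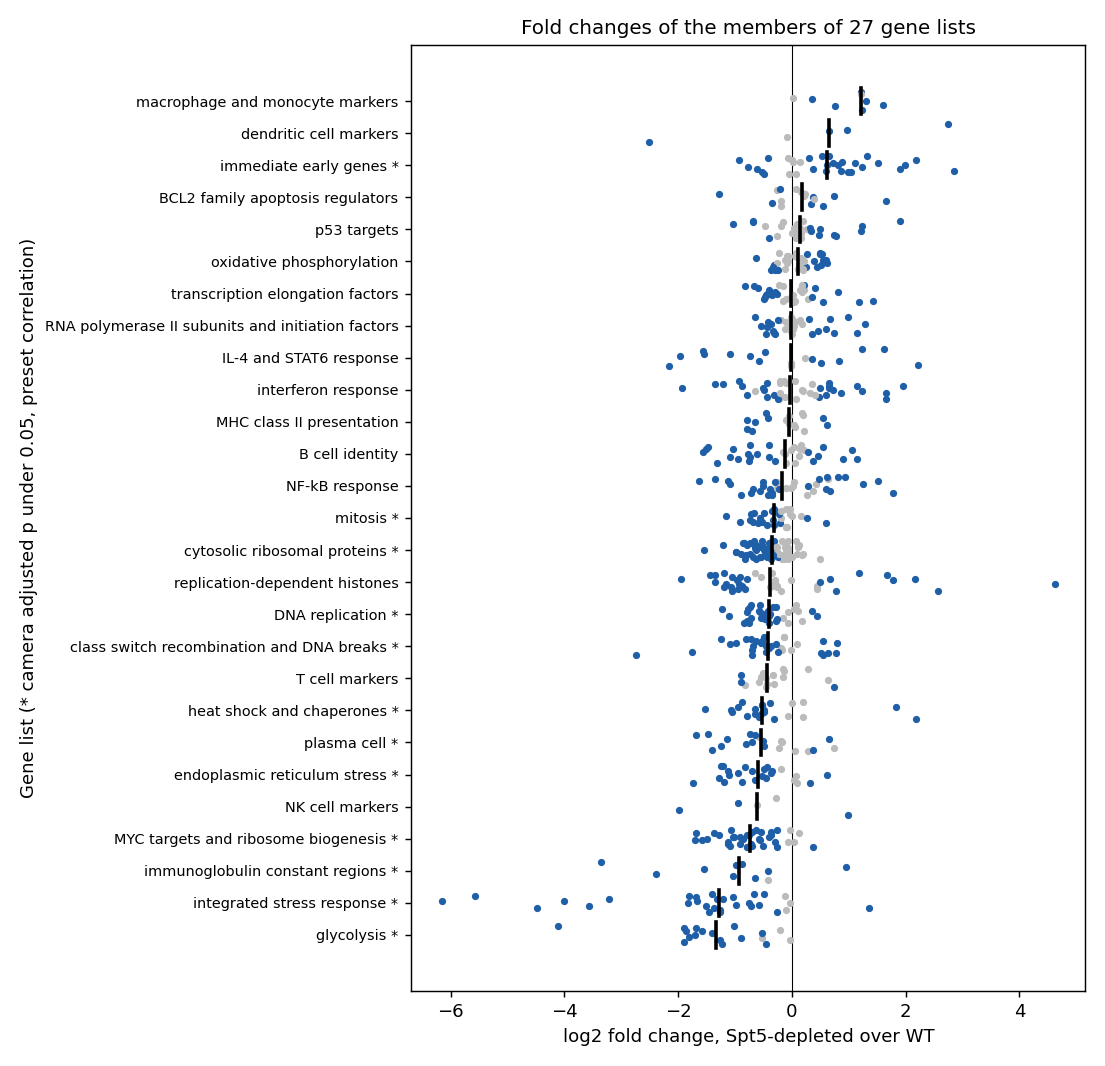
Log2 fold change (Spt5-depleted over WT, 3 libraries each) of every tested member of the 27 tested gene lists, a point per gene, blue where the edgeR adjusted p is under 0.05 and grey otherwise, with a black bar at each list's median. Glycolysis (median -1.34) and the integrated stress response (-1.29) lie farthest to the left, and asterisks mark lists called by camera with its preset correlation.

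Of 4 tested lists of markers of other cell types that a spleen culture can hold, 0 were called, and fry called the dendritic cell list higher (adjusted p = 0.014). Of 8 macrophage and monocyte markers 6 rose, with 7 adjusted over the list alone, and the list was not called (median log2 fold change 1.21, camera adjusted p = 0.0853). It was called higher without Spt5-depleted replicate 1 (adjusted p = 0.00563) and with the replicate number as a block (adjusted p = 0.0241). Cd14 had 2.38 ± 0.20 and 5.56 ± 2.31 CPM and Mrc1 0.41 ± 0.05 and 1.03 ± 0.17 CPM (SD, n = 3 each; adjusted p = 0.00212 and 0.00392). Of 5 dendritic cell markers 3 rose, including Xcr1 (2.75) and Cst3 (0.97), and 1 fell, Batf3 (-2.52) (camera adjusted p = 0.402). Of 17 T cell markers 2 fell, Cd2 (-0.90) and Lck (-0.89), and 1 rose, and of 5 natural killer cell markers Gzmb (-1.99) and Gzma (-0.95) fell and Eomes (1.00, at 0.57 CPM in WT) rose (camera adjusted p = 0.266 and 0.344). The T cell list was called lower without Spt5-depleted replicate 2 (adjusted p = 0.0339). The Eomes call was lost without WT replicate 1, WT replicate 3 or Spt5-depleted replicate 2 (log2 fold changes 0.91, 0.94 and 0.68, adjusted p = 0.0664, 0.0626 and 0.16). It was also lost under DESeq2's Wald test (Eomes log2 fold change 0.98, adjusted p = 0.0789). The neutrophil, platelet, stromal and erythroid lists had 4, 2, 3 and 0 tested members and were not tested as groups. Of these members 1 neutrophil, 1 platelet and 1 stromal marker rose and 0, 1 and 2 fell.

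With the inter-gene correlation estimated from the libraries, 0 of the 12 called lists passed camera's test at an adjusted p under 0.05 and 2 lists had an unadjusted p under 0.05, while fry called 4 lists higher and 13 lower. At an adjusted p under 0.05, the authors' deposited table had, by direction, 3719 higher and 3622 lower genes. Of the genes called here, 7036 were called in the same direction in the authors' deposited table and 0 in the opposite direction.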

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

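The thinning of counts described here was chosen after seeing the data. The counts of 3822 higher and 3685 lower genes stayed within 1.5 times under every other scaling, filter and test tried, with the replicate block and at an adjusted p under 0.01, and 0 called genes changed sign under any of the scalings, filters, tests or left-out libraries. With a 2-fold minimum, which by construction keeps fewer genes, 1187 were higher and 917 lower. Leaving out a library gave 3431 to 3783 higher and 3281 to 3678 lower genes. Thinned to the depth of the smallest library, the counts gave 3732 higher and 3593 lower genes, so depth alone did not set these numbers. The Supt5 log2 fold change lay between -4.11 and -3.77 throughout. The 1 list called higher and the 11 called lower depended on the set test. With an estimated correlation the numbers were 0 and 0, and fry called 4 higher. The mitosis list had an estimated correlation of -0.018, below the preset 0.01. Its camera adjusted p still went from 0.00129 to 0.41. A lost call therefore does not by itself show that the genes of a list vary together. What else caused the losses was not tested. Leaving out a library gave 1 to 2 lists higher, the added list being the macrophage and monocyte markers without Spt5-depleted replicate 1. Under library totals alone, the same 12 lists were called. The medians of 6 lists that were not called changed sign between scalings: B cell identity, interleukin 4, MHC class II, interferon, elongation factors, and polymerase subunits and initiation factors. Same-numbered libraries did not deviate together (correlations 0.038, -0.040 and -0.005 across genes), so the numbers are not taken as pairs; with the replicate block 3755 genes were higher and 3615 lower, and 2 lists were higher, the added one again the macrophage and monocyte markers. Of 117 named genes 8 crossed the threshold under some alternative and 0 changed direction. In simulated counts with few changed genes 4.17% of 1.2-fold changes were recovered, a share that does not carry over to these data. Depth and replicate number were not varied there. The gene length trend was not run.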

Other observations

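The groups described next were defined by gene names after the data were seen, and the tests of sex, scaling, background reads and overlapping transcripts were also chosen only after the results were seen. The variable segments of the immunoglobulin genes were lower as groups in Spt5-depleted cells. Of 82 tested heavy chain V segments 65 fell and 0 rose (median log2 fold change -1.15, limma camera adjusted p = 1.80e-08; adjusted p = 0.48 with an estimated correlation), and of 93 kappa V segments 53 fell and 0 rose (median -0.62, camera adjusted p = 5.79e-07; adjusted p = 0.48 with an estimated correlation). Related segments share reads, so single members are uncertain. Of 309 zinc finger genes named Zfp 155 rose and 45 fell (median 0.36, camera adjusted p = 0.000146; adjusted p = 0.22 with an estimated correlation). Of 22 small nucleolar RNA genes 10 fell and 3 rose (median -0.79, camera adjusted p = 0.11). Small nucleolar RNA without a poly(A) tail may be missed in these libraries.

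Loci that carry only a clone or model name rose as a group. Of 537 tested Rik loci 290 rose and 78 fell (median log2 fold change 0.57, camera adjusted p = 4.81e-07; adjusted p = 0.024 with an estimated correlation), and of 171 Gm loci 88 rose and 14 fell (median 0.74, camera adjusted p = 5.13e-06; adjusted p = 0.094 with an estimated correlation). Across all genes of the table, the 1692 with a mean of up to 0.3 CPM had a median log2 fold change of 0.34, and the 578 above 300 CPM had -0.26, with 114 higher and 298 lower.

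Spt5 depletion came with lower Ighg1, Ighe, Ighg2b and Ighg3 mRNA, and the design gives loss of Spt5 as a biological explanation. A smaller share of cycling cells would lower the cell cycle lists alike, to -1 or below by the bound set before the lists were examined. Their medians were -0.31 for mitosis (95% bootstrap interval over genes -0.47 to -0.15) and -0.41 for DNA replication (-0.57 to -0.28). Library totals alone gave -0.15 and -0.25. These values argue against fewer cells cycling at harvest as the whole cause. The intervals do not cover the spread between libraries, and divisions earlier in the culture were not measured. Dilution by other cell types would lower B cell genes alike and raise the markers of the others; the median of the B cell identity list was -0.13 (-0.67 to 0.09; 0.03 with library totals alone), above that same bound, and those of the T cell and natural killer cell lists were -0.44 and -0.62. Other values go with some dilution. Of 8 macrophage markers 6 rose and 0 fell (median 1.21). Camera called that list without Spt5-depleted replicate 1 and with the replicate block (adjusted p = 0.00563 and 0.0241). Its main camera fit gave an adjusted p = 0.0853. Fry called the dendritic cell list higher (adjusted p = 0.014) and B cell identity lower (adjusted p = 0.00172). Camera called neither (adjusted p = 0.402 and 0.0832). Fry compares with no other genes and called 4 lists higher and 13 lower, so its calls do not single out dilution. Of 5 dendritic cell markers 3 rose and 1, Batf3, fell (-2.52). The intervals for DNA replication and B cell identity reach past -0.5, the bound set for excluding these explanations outright, so a partial contribution of either stays open, and sex cannot be told apart from genotype, since 0 libraries had an Xist level that went with the other group.

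The integrated stress response and glycolysis lists were lower by camera with its preset correlation, calls that were lost with an estimated correlation (adjusted p = 0.41 for each). Scaling would have to bring their medians near 0. With library totals alone the medians were -1.13 (95% bootstrap interval -1.44 to -0.71) and -1.18 (-1.60 to -0.61). The choice between TMM and library totals therefore did not produce the falls. That choice moved the median of all genes only from 0.005 to 0.164, so it could not have brought medians of -1.29 and -1.34 near 0. A change in total mRNA per cell was not measured, so scaling as a cause cannot be decided. A candidate explanation for the first list is a lower level of Atf4 mRNA, which encodes its main activator: Atf4 had a log2 fold change of -1.68 (-1.88 to -1.47, 2 SE either side), past the bound of -1 set before its value was seen. Atf4 is itself a member of that list, so this shows that it fell with the others and not that it led them. Medium and cell density were not recorded in the labels, and sex and Spt5 stay open.

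An even background of reads in the depleted libraries could raise poorly expressed loci such as the Rik and Gm loci. It would add about 0.006 on the log2 scale at 10 CPM, from the median gain of 0.04 CPM of genes under 1 CPM, and the 228 Rik and Gm loci with a mean of at least 10 CPM had a median of 0.24 (95% bootstrap interval 0.13 to 0.34). Under 10 CPM, the median of 480 such loci exceeded that of other genes of the same mean CPM by 0.87 (0.74 to 1.02), where an even background would raise both alike. Reads of overlapping or neighbouring transcripts cannot be told apart from a rise of the loci themselves: the median was 1.06 for 152 loci with the overlap suffix and 0.52 for 556 without it, and what the suffix marks is not stated. The rise may therefore be biological or come from transcription that runs into these loci.

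The 6 libraries can be split into 3 and 3 in 10 ways, too few for a share under 0.05. The real split gave 3822 higher and 3685 lower genes by edgeR, the only 1 of the 10 to give as many. The highest of the other splits gave 0 in either direction, with at most 87 genes at an unadjusted p under 0.05. For gene lists the real split gave 1 higher and 11 lower by camera, and the highest other split gave 12 in one direction. The direction of another split is arbitrary, so each was scored by the larger of its 2 directions. As many lists were then reached in 10 of the 10 splits for the higher count and in 3 of the 10 for the lower count. The other splits still hold 2 libraries of one genotype against 1, so they keep part of the real difference. For single genes that difference also widens the spread within each of their groups, which lowers their counts of called genes. List calls of the other splits followed the genotype in the majority. With 2 WT libraries in the first group, more lists were lower than higher in the other group. With 2 depleted libraries in the first group, more were higher than lower. Neither the gene counts nor the list counts of the other splits can therefore decide whether the real counts arose by chance.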
